A study of Anas platyrhynchos with 7 samples.

How the data were processed

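Spleen RNA from ducks infected with duck enteritis virus (DEV), a herpesvirus of waterfowl, was profiled in 7 libraries made with an Ion Torrent total RNA kit and read on an Ion Proton instrument, per the labels' protocols. The deposited count table holds whole-number read counts per gene for 16191 genes, and the deposited RPKM table holds RPKM values, that is reads scaled for gene length and library total, for the same genes, per the file headers. The RPKM values were made by the authors from those counts, and their denominators follow each library's total count. The aligner, the counting tool, the genome build and any use of strand are not given in the sources used here. Reads of near-identical gene copies, such as immunoglobulin, globin and histocompatibility genes, could therefore have been split in ways that cannot be checked, and values of such genes are uncertain.

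Gene names were taken from the files for 10725 genes. Of 5466 genes listed by a LOC number, 2898 were found in a RefSeq table of the assembly IASCAAS_PekinDuck_T2T and 1561 received a symbol from it. A further 355 were named by the authors' BLAST symbol, and 3550 genes stayed without a symbol. The table was used for names, and no coordinates are given.

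Total counts ran from 9661395 in the control to 13664772 in the titer 10-2 library at 114 h. A count of 0 in a library allowed up to 0.311 CPM in the control and 0.22 CPM in the deepest library, taking 3 counts as the limit. Intervals of shares are Wilson 95% intervals. Intervals and limits cover counting error only, since the reads carry no molecular identifiers.

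Counts were tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3 (TMM scaling, robust fitting) and adjusted by the Benjamini-Hochberg method at 0.05. The test gives no standard error. The SE of a log2 fold change is its absolute value divided by the square root of its F statistic, and is approximate. Genes with a mean of at least 1 CPM over the 7 libraries entered, which left 11791. Each titer and time had 1 library, so spread was estimated across times or across titers. Comparisons of infection or of a titer with the control used 3 arms, and comparisons of a time with the control used 4 time levels, over all 7 libraries in both cases. The titers were compared with each other, and the times with each other, in the 6 infected libraries with both factors in 1 model, which left 2 residual degrees of freedom. The single control library was assumed to vary like the infected ones, and all comparisons with it share its chance values. An interaction of titer and time leaves no residual degrees of freedom and was not tested. Whether a library came from 1 bird or from several is not stated, so adjusted p-values measure the spread between these libraries.

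The choice of genes to name was made before the data were examined, as were the designs, the alternatives and 28 gene lists. For the infection, titer and late-against-early comparisons the rule took the 8 highest and the 8 lowest log2 fold changes among passing genes with a symbol and a mean of at least 4 CPM. Where none passed, it took the 5 genes of smallest p. From each list it took up to 4 passing members or, where a list had none, up to 2 members of highest mean CPM. The other comparisons took 3 in each direction. Genes outside the rule are said to have been chosen after their values were seen.

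Lists with at least 5 tested members were tested with camera (preset correlation 0.01, and again with an estimated correlation) and fry from limma 3.58.1 on log2 CPM with a prior count of 2, adjusted over the lists of a comparison. The list of pancreas genes had 1 tested member and was left out, so 27 lists were tested. An immunoglobulin list was added after the values were seen and was adjusted together with those 27. For single libraries, the median log2 ratio of a list to the control was placed among 10000 random lists of the same size matched on mean expression.

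Each comparison was repeated with RLE size factors, without the filter, with a minimum mean of 4 CPM, with DESeq2 1.42.0, without robust fitting, with limma-trend on log2(RPKM + 0.5), with other designs and without each infected library in turn. A term for the state of 8 genes that were higher in 3 libraries than in the other 4 was added after seeing the data. The test was tested on simulated data with 200 changed genes. Of genes changed 4-fold, 68.8% were called in the infection comparison (11688 genes), 84.8% in the titer comparison (11705 genes) and 79.1% in the comparison of 114 h with 66 h (11713 genes). Genes changed 2-fold were called in 18.2%, 40.3% and 26.9% of cases. In the comparison of 66 h with the control (11692 genes), 60.6% of 4-fold and 7.46% of 2-fold changes were called. The many simulated changes make the Benjamini-Hochberg cut less strict than in the real comparisons, which had few or no calls. These shares are therefore likely too high for the real data. Unchanged genes gave 13, 15 and 13 calls in the first 3 comparisons and 14 in that of 66 h, which is more than 5% of all calls, so some single calls could be false. A list of 30 genes raised 2-fold was also simulated for 114 h against 66 h. Camera gave it adjusted p = 9.07e-40 with the preset correlation and 0.0849 with an estimated correlation, and fry gave adjusted p = 0.0347. The simulated genes were drawn independently, whereas the tested lists reached an estimated correlation of 0.876 (ribosomal protein genes, between the titers). For lists that vary together the preset correlation makes p-values too small, and the simulation does not show by how much. A call lost with an estimated correlation does not show that a list was unchanged. Nor does a call with the preset one show that it changed.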

Results

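Spleens of 50-day-old ducks were collected 66, 90 or 114 h after injection of DEV into the leg muscle at either of 2 titers, and 1 control was injected with saline. The labels write the titers as 100 and 10-2. They may be powers of 10 that lost their superscripts, and 100 is the higher under either reading. There was 1 library for each of the 6 combinations of titer and time and 1 control library at 0 h, so no value for a single library has a replicate check. The total count was 9661395 in the control, between 10231231 and 10614482 in the 3 titer 100 libraries, and between 9807338 and 13664772 in the 3 titer 10-2 libraries. Spearman correlations between libraries, across genes, ran from 0.954 to 0.981.

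The first comparison asked how infected spleens differed from the control. Immunoglobulin transcripts stood out. LOC101800699, annotated as an immunoglobulin lambda-like gene, took 1.63% of all counts in the control (Wilson 95% interval 1.62 to 1.64%) and between 2.55% (2.54 to 2.56%) and 6.6% (6.58 to 6.61%) in the infected libraries. It was not called (log2 fold change 1.51 ± 0.60 SE, edgeR adjusted p = 1). Of 29 tested immunoglobulin genes, a group chosen after its values were seen, 26 had a positive log2 fold change, with a median of 1.16. The camera test placed the group above other genes (adjusted p = 3.42e-15), and the call was lost with adjusted p = 0.601 with an estimated correlation. IGJ, which joins secreted IgM and IgA, was at 2628 CPM in the control and between 3108 and 6157 CPM in the infected libraries. For LOC101800699 and IGJ the lowest infected libraries were titer 10-2 at 90 h and 114 h. Those libraries, like the control, were high in the W-type genes described with the titers.

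No single gene passed the test of infection. With edgeR 0 of 11791 genes were called, 508 had an unadjusted p under 0.05, DESeq2 called 10 and limma on RPKM called 1. Without the titer 10-2 library at 90 h, edgeR called 1. LOC101803474, an RNA without a symbol, had the smallest adjusted p (0.0554) and was higher in infected birds. Among genes with a symbol and a mean of at least 4 CPM, the 5 of smallest p were lower in infected birds and did not pass. PDE4B, a phosphodiesterase that degrades cyclic AMP, had a log2 fold change of -1.54 ± 0.23 (SE), with 88.6 CPM in the control against 22.7 to 43.1 CPM. The complement protease gene C1S had -1.24 ± 0.25, the matricellular genes CYR61 and CTGF had -1.76 ± 0.36 and -1.21 ± 0.25, and the somatostatin receptor gene SSTR5 had -1.85 ± 0.39.

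Among the fixed lists, camera placed 9 apart from other genes in the infected birds, and none was called with an estimated correlation. Tested for a shift in 1 direction, fry called 0 of 27 lists for infection and for either titer against the control. Ribosomal protein genes stood higher (52 of 62 members, adjusted p = 5.62e-09; adjusted p = 0.624 with an estimated correlation), with RPS4X at 0.99 ± 0.32 and RPSA at 0.24 ± 0.34. Genes of oxidative phosphorylation followed them (47 of 57, adjusted p = 0.000318; adjusted p = 0.73 with an estimated correlation). Neither list was called in titer 10-2 alone (adjusted p = 0.0726 and 0.874), and in titer 10-2 at 90 h their medians were -0.23 and -0.25. Granulocyte genes stood higher in 11 of 12 members (adjusted p = 0.00596; adjusted p = 0.624 with an estimated correlation), among them LYZ, coding for lysozyme, at 2.65 ± 1.08 and LCN8 at 1.74 ± 1.01. Heat shock genes stood higher in 21 of 22 members (adjusted p = 0.00041; adjusted p = 0.624 with an estimated correlation), with HSP90AA1 at 0.79 ± 0.60 and HSPA8 at 0.61 ± 0.44, but not at 66 h, where their medians were 0.01 and -0.15. Immediate early genes, which respond within minutes to stimuli and to handling, stood lower in 15 of 21 members (adjusted p = 0.00041; adjusted p = 0.624 with an estimated correlation), and BTG2 had -0.69 ± 0.27. Stromal matrix, cell cycle, erythroid and plasma cell genes were the other 4 lists, all higher (adjusted p = 0.00118, 0.000637, 0.0443 and 0.0108; adjusted p = 0.624 with an estimated correlation for each).

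Genes of the interferon response, the main antiviral programme of vertebrate cells, were not called higher or lower as a list (camera adjusted p = 0.107), and their medians in single libraries ran from -0.38 in titer 10-2 at 66 h to 0.30 in titer 100 at 114 h. Among them ZNFX1 had a log2 fold change of -0.06 ± 0.31. The T cell and B cell lists were not called over all infected libraries (camera adjusted p = 0.329 and 0.977), with CD3E at -0.03 ± 0.27 and CR1 at 0.24 ± 0.27. The T cell median was -0.43 in titer 100 and 0.58 in titer 10-2 at 90 h and between 0.03 and 0.20 in the other 4 libraries. The antigen presentation genes B2M and CD74 had -0.21 ± 0.42 and 0.07 ± 0.32. Over each list alone, 4 immediate early and 2 acute phase and complement genes passed when adjusted over the list alone, all lower, and none passed over all genes.

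**Figure D1:**
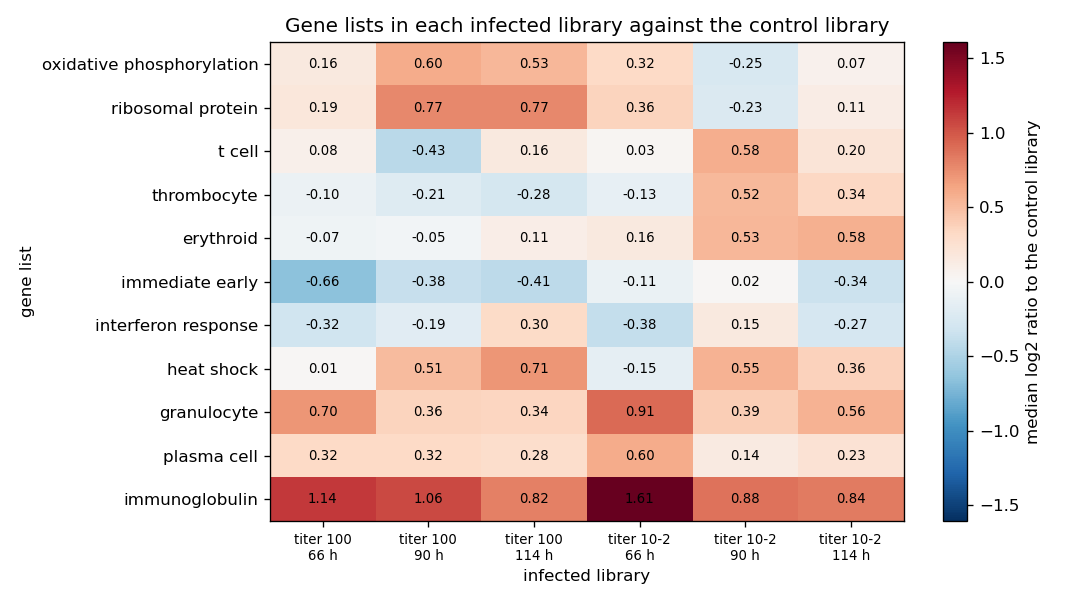
Median log2 ratio of each gene list (vertical axis) in each infected library (horizontal axis) to the single control library, by color and printed value; the immunoglobulin list was chosen after its values were seen. Immunoglobulin medians lay between 0.82 and 1.61, and ribosomal protein medians between -0.23 and 0.77.

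Against the control, the titer 100 libraries raised 1 transcript past the threshold. LOC101803474, uncharacterized and outside the naming rule, rose by 4.33 ± 0.45 on the log2 scale (edgeR adjusted p = 0.0326), from 4 CPM in the control to 76.3, 72.4 and 92.5 CPM at 66, 90 and 114 h. It was also at 30.7 to 57.2 CPM in the titer 10-2 libraries. The call was lost without the titer 100 library at 66 h, 90 h or 114 h and without the titer 10-2 library at 114 h, and also with a further term for W-type genes, described with the titers, that was chosen after seeing the data. Without the titer 10-2 library at 66 h, 11 genes were called. Below the threshold, SSTR5 was at -2.75 ± 0.45 and PDE4B at -1.74 ± 0.25 in titer 100, and SMC2, a condensin gene, at 1.14 ± 0.23. DESeq2 called 20 genes. All 62 ribosomal protein genes and 51 of 57 genes of oxidative phosphorylation stood higher in titer 100 than in the control (camera adjusted p = 1.97e-18 and 1.33e-11; adjusted p = 0.524 with an estimated correlation for both). Cell cycle (41 of 49), heat shock (21 of 22) and plasma cell genes (13 of 17) stood higher too (camera adjusted p = 5.07e-05, 5.58e-05 and 0.0175). Immediate early genes stood lower in 16 of 21 members (camera adjusted p = 0.000171). With an estimated correlation each of these lists had adjusted p = 0.524.

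The titer 10-2 libraries gave 0 edgeR calls against the control, with 506 genes at an unadjusted p under 0.05, 12 called by DESeq2 and 1 by limma on RPKM. Without the titer 10-2 library at 90 h 1 gene was called. PDE4B was again lower (-1.34 ± 0.25), as were the cilium-related genes TTLL9 (-1.74 ± 0.34) and NME5 (-1.80 ± 0.36), none past the threshold. Erythroid genes stood higher in 20 of 27 members (camera adjusted p = 0.000519; adjusted p = 0.65 with an estimated correlation), and granulocyte genes in 11 of 12 (adjusted p = 0.00424; adjusted p = 0.65 with an estimated correlation). Stromal matrix genes stood higher in 32 of 41 members (adjusted p = 0.000246; adjusted p = 0.675 with an estimated correlation). T cell genes stood higher in 22 of 30 and heat shock genes in 19 of 22, while immediate early genes stood lower in 12 of 21 and interferon response genes in 28 of 38 (adjusted p = 0.0237, 0.0237, 0.00776 and 0.0452; adjusted p = 0.732 with an estimated correlation for each).

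At 66 h, SERPINB10 rose over both titers. This gene, listed as LOC101798932 and described as similar to MENT, a serpin that condenses chromatin in avian granulocytes, was outside the granulocyte list and rose by 4.76 ± 0.38 on the log2 scale (edgeR adjusted p = 0.0142), from 3.8 CPM in the control to 103 CPM in each 66 h library. It was the single call at 66 h, where 416 genes had an unadjusted p under 0.05 and DESeq2 called 39. The call was lost without either 66 h library. The count was 3 and 4 without the titer 100 library at 90 h or 114 h and 5 and 4 without the titer 10-2 library at those times. Granulocyte genes as a list stood higher in 9 of 12 members (camera adjusted p = 2.86e-05; adjusted p = 0.37 with an estimated correlation), and 3 passed when adjusted over the list alone. Interferon response genes stood lower in 32 of 38 members (adjusted p = 9.19e-06; adjusted p = 0.784 with an estimated correlation), with medians of -0.32 and -0.38 in the 2 libraries. Immediate early genes stood lower in 14 of 21 (adjusted p = 9.19e-06; adjusted p = 0.37 with an estimated correlation), and 6 passed when adjusted over the list alone. Tested for a shift in 1 direction, fry called 0 of 27 lists (smallest adjusted p = 0.279). In both directions together, it called the acute phase and complement, immediate early, granulocyte and plasma cell lists (mixed adjusted p = 0.000265, 0.00545, 0.0124 and 0.0194). Camera did not call the acute phase and complement list (adjusted p = 0.619), and placed plasma cell genes higher (adjusted p = 0.000212; adjusted p = 0.37 with an estimated correlation).

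At 90 h and 114 h edgeR called 0 genes against the control, with 346 and 366 genes at an unadjusted p under 0.05; DESeq2 called 4 and 19 and limma on RPKM called 0 at both times. Without the titer 10-2 library at 90 h, 3 genes were called at 90 h and 2 at 114 h, and without the titer 100 library at 114 h 1 gene was called at 114 h. Among genes with a symbol and a mean of at least 4 CPM, those of smallest p at 114 h were lower without passing in edgeR, among them the immediate early genes NR4A1 and NR4A3. NR4A1 was at -4.06 ± 0.49 (43.7 CPM in the control, 1.82 and 3.32 CPM at 114 h), NR4A3 at -3.22 ± 0.40, CYR61 at -2.26 ± 0.32 and APOLD1 at -4.85 ± 0.78. DESeq2 called each of these genes at 114 h. Heat shock genes stood higher in 21 of 22 members at both times (camera adjusted p = 1.73e-08 and 9.52e-11; adjusted p = 0.818 and 0.648 with an estimated correlation). Granulocyte genes stood higher in 11 of 12 members at both times (camera adjusted p = 0.0179 and 0.00184, and again 0.818 and 0.648 with an estimated correlation). Camera called 8 lists at 90 h and 11 at 114 h, not all of them named here. At 90 h IGFBP5, coding for a binding protein of insulin-like growth factors, was at 1.80 ± 0.42 and NR4A1 at -2.13 ± 0.47, neither of which passed. In both directions together, fry called the acute phase and complement list at 90 h and the immediate early list at 114 h (mixed adjusted p = 0.00613 and 0.0141), and in 1 direction it called 0 lists at either time. Camera did not call the former (adjusted p = 0.454) and placed the latter lower (adjusted p = 4.3e-08; adjusted p = 0.548 with an estimated correlation).

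Between the titers, matched by time, edgeR called 0 genes, 798 had an unadjusted p under 0.05, DESeq2 called 23 and limma on RPKM 0. Of the 5 genes of smallest p with a symbol and a mean of at least 4 CPM, none passed. UQCRH, coding for a subunit of complex III, was higher in titer 100 by 1.71 ± 0.22, ATP5J2, coding for a subunit of ATP synthase, by 1.57 ± 0.23, HAAO, an enzyme gene of tryptophan breakdown, by 1.98 ± 0.34 and STRIP2 by 0.96 ± 0.18, and SSTR5 differed by -1.86 ± 0.33. Every one of 62 ribosomal protein genes and 56 of 57 genes of oxidative phosphorylation had a positive difference (camera adjusted p = 5.02e-15 for both; adjusted p = 0.814 with an estimated correlation for both). Heat shock and cell cycle genes stood higher and stromal matrix genes lower (adjusted p = 0.0152, 0.0233 and 0.014; adjusted p = 0.814 with an estimated correlation for each). In 1 direction fry called 0 of 27 lists between the titers (smallest adjusted p = 0.111). The ribosomal protein difference was not present at each time, since the ribosomal protein median of titer 100 minus titer 10-2 was -0.22 at 66 h, 0.99 at 90 h and 0.59 at 114 h. For oxidative phosphorylation it was -0.14, 0.84 and 0.42 at the same times. Erythroid genes stood lower in titer 100 in 17 of 27 members (adjusted p = 2.41e-05; adjusted p = 0.814 with an estimated correlation), and 9 passed when adjusted over the list alone. The globin genes LOC101798480 and LOC101798111 had -0.93 ± 0.26 and -1.30 ± 0.26. T cell genes (25 of 30) and thrombocyte genes (15 of 18) stood lower as well (adjusted p = 0.000374 and 0.00395; adjusted p = 0.814 with an estimated correlation for both). In titer 100 and titer 10-2 the T cell medians against the control were 0.08 and 0.03 at 66 h, -0.43 and 0.58 at 90 h, and 0.16 and 0.20 at 114 h. Most of the T cell difference thus lay at 90 h. Thrombocyte medians were -0.10 and -0.13 at 66 h, -0.21 and 0.52 at 90 h, and -0.28 and 0.34 at 114 h, so that difference was absent at 66 h.

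The titers also differed in a set of genes chosen after their values were seen. These 8 genes of families that have a W-linked copy in birds, among them LOC101791000 (hnRNP K-like) and LOC101805329 (KCMF1-like), had medians of 13.4, 13.8 and 13.1 CPM in the control and in titer 10-2 at 90 h and 114 h, and medians between 0.579 and 1.85 CPM in the other 4 libraries. The titer comparison, the comparisons with the control and the ribosomal protein medians therefore vary together with these genes. So does LOC101800699, with 1.63, 2.55 and 3.29% of counts in the libraries high in them and 3.81 to 6.6% in the other 4. IGJ was at 2628, 3108 and 3892 CPM against 4367 to 6157 CPM. Medians of the immunoglobulin list did not divide that way, at 0.88 and 0.84 in titer 10-2 at 90 h and 114 h and 0.82 in titer 100 at 114 h. Leaving out 1 infected library at a time gave between 1 and 34 calls between the titers. The 2 highest counts, 34 and 32, came without titer 100 at 114 h and without titer 10-2 at 114 h, in fits of 5 libraries. In both fits the remaining 114 h library is matched exactly by its own time term. The titer difference then rests on the same 66 h and 90 h libraries, so these are not separate results. Leaving out titer 100 at 66 h, titer 100 at 90 h, titer 10-2 at 66 h or titer 10-2 at 90 h gave 6, 2, 3 or 1, and the same holds for the fits of each time.

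**Figure D2:**
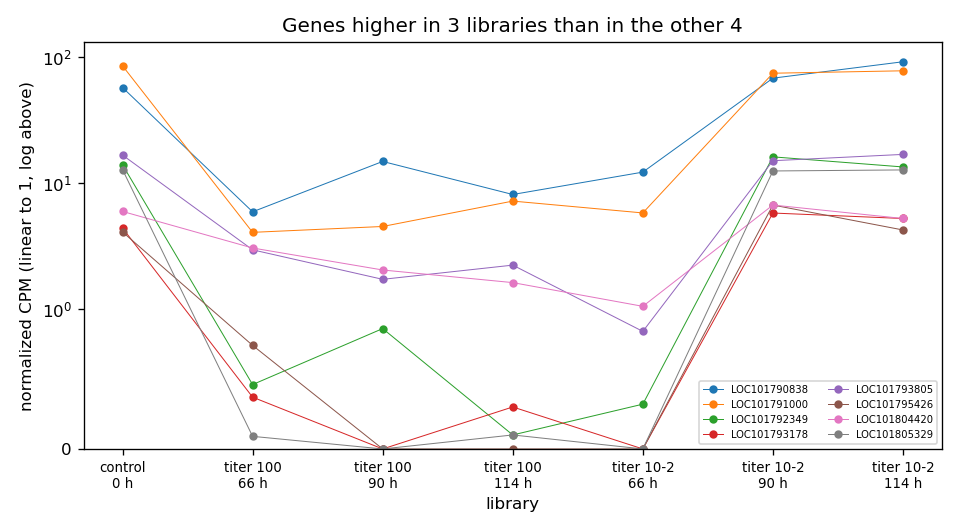
Normalized CPM (vertical axis, linear to 1 and logarithmic above) of 8 genes chosen after their values were seen, 1 line per gene, in each library (horizontal axis); lines join values of a gene and no order is meant. LOC101791000 was at 74.5 to 85.2 CPM in the control and in titer 10-2 at 90 h and 114 h and at 4.06 to 7.19 CPM in the other 4 libraries.

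From 66 h to 114 h 4 genes fell, and 0 rose. SERPINB10 fell by 3.85 ± 0.26 on the log2 scale (edgeR adjusted p = 0.00229), and PROK2, a secreted peptide that attracts leukocytes, fell by 5.24 ± 0.50 (adjusted p = 0.0173) from 21.3 and 12.5 CPM to 0.405 and 0.424 CPM. MMP9, a gelatinase stored in granulocytes and a member of the granulocyte list, fell by 2.65 ± 0.31 (adjusted p = 0.0459). LOC101802154, outside the naming rule and given the symbol S100A9 in the authors' BLAST column, fell by 3.98 ± 0.39 (adjusted p = 0.0173) from 1294 and 1624 CPM to 60.3 and 131 CPM. In all 4 genes both 66 h libraries were higher than every other library. Over the granulocyte list alone, 2 members passed lower and 1 passed higher at 114 h when adjusted over the list alone. Of its other genes, LYZ was at 154 and 167 CPM at 66 h and at 21.7 and 107 CPM at 114 h, without passing. The granulocyte list was not called (6 of 12 members negative, camera adjusted p = 0.0809; adjusted p = 0.856 with an estimated correlation). That list also names S100A9, but LOC101802154 was not given this symbol here and so was not tested within it.

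**Figure D3:**
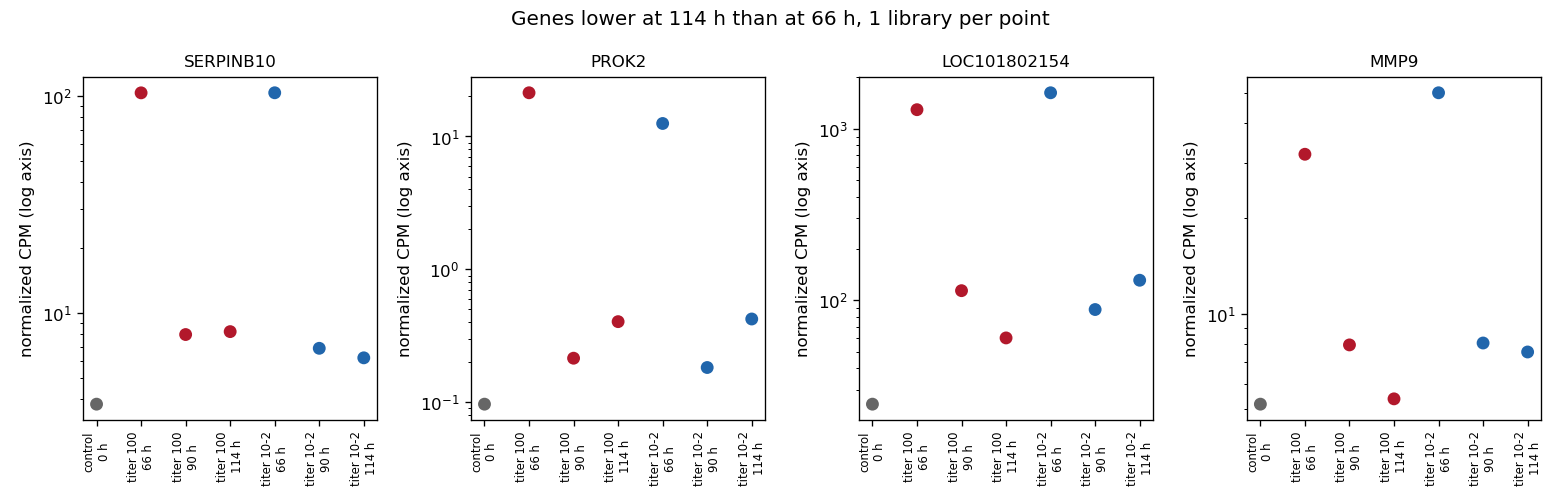
Normalized CPM (vertical axes, logarithmic) of the 4 genes that fell from 66 h to 114 h, 1 point per library (horizontal axes), gray for the control, red for titer 100 and blue for titer 10-2. SERPINB10 was at 103 CPM in both 66 h libraries and at most 8.21 CPM elsewhere.

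Heat shock genes stood higher at 114 h than at 66 h in 20 of 22 members (camera adjusted p = 2.9e-12; adjusted p = 0.856 with an estimated correlation), and 9 passed when adjusted over the list alone. HSP90AA1 was at 1507 and 1253 CPM at 66 h and at 4409 and 2381 CPM at 114 h, a log2 difference of 1.26 ± 0.35 that did not pass over all genes. Interferon response genes stood higher at 114 h in 33 of 38 members (adjusted p = 5.02e-07; adjusted p = 0.856 with an estimated correlation). Their medians against the control were -0.32 at 66 h and 0.30 at 114 h in titer 100, and -0.38 and -0.27 in titer 10-2, so most of that difference lay in the titer 100 library at 114 h. Genes of cholesterol synthesis stood lower in 19 of 20 members, plasma cell genes lower in 12 of 17, and erythroid and smooth muscle genes higher in 20 of 27 and 13 of 17 (adjusted p = 0.00208, 0.00766, 0.00208 and 0.000942; adjusted p = 0.856 with an estimated correlation for each). For 114 h against 66 h fry called 0 of 27 lists in 1 direction (smallest adjusted p = 0.454). In this comparison 540 genes had an unadjusted p under 0.05, DESeq2 called 33 and limma on RPKM called 5. No gene was called when time entered as a straight line, and without 1 library the count ran from 2 (titer 10-2 at 66 h) to 49 (titer 100 at 114 h). Without titer 10-2 at 114 h it was 45, and without the others 7 (titer 100 at 66 h and titer 10-2 at 90 h) and 8 (titer 100 at 90 h). Without either 66 h library SERPINB10 stayed called and PROK2, MMP9 and LOC101802154 did not, and the same held with the added term for W-type genes. MMP9 was also lost with RLE size factors, without robust fitting, with limma on RPKM and without the titer block.

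A test for any difference among the 3 times called 7 genes, the 4 above and 3 outside the naming rule, and DESeq2 called 52. TGM3, named by BLAST and coding for a transglutaminase, was at 47.1 and 22.8 CPM at 66 h and at most 6.69 CPM in the other libraries (adjusted p = 0.0274). LOC101792157, annotated as similar to a class I histocompatibility chain, ran from 0.43 to 66.3 CPM over the infected libraries, lowest at 90 h (adjusted p = 0.0136). LOC101804125, uncharacterized, was highest at 90 h with 603 and 357 CPM against at most 98.9 CPM in every other library (adjusted p = 0.0274). Without titer 10-2 at 114 h 108 genes were called and without titer 100 at 114 h 85, against 11, 15, 5 and 11 without titer 100 at 66 h, titer 100 at 90 h, titer 10-2 at 66 h and titer 10-2 at 90 h. Without either 66 h library 3 of the 7 genes stayed called, and LOC101804125 and LOC101792157 were each lost without a 90 h library.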

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

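All tests in this part were chosen after the result was seen. The genes that passed the comparison of 114 h with 66 h were marked because their change since the control differed between those times by a direct test. The log2 differences, 114 h minus 66 h, were -5.24 for PROK2, -3.85 for SERPINB10, -3.98 for LOC101802154 and -2.65 for MMP9.

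Of these 4 genes, MMP9 alone was tested in the granulocyte list, which also names S100A9, the BLAST symbol of LOC101802154. Blood left in the spleen pieces was weighed first for the 4 genes. The mean erythroid log2 difference of 66 h minus 114 h was -0.335 ± 0.142 (SE over 27 genes, taken as independent), and the summed globin level at 66 h was 2867 CPM in titer 100 and 5488 CPM in titer 10-2 against 1991 and 4867 CPM at 90 h and 2142 CPM in the control. Globin at 66 h was thus above 90 h and the control, the direction that blood predicts, but by far less than the 4 genes were. It was below 114 h (5341 CPM in titer 100 and 10450 CPM in titer 10-2), opposite to the 4 genes. These values argue against more whole blood of unchanged makeup as the cause. Globin cannot show whether that blood held more granulocytes. As to sex, taken up again among the other observations, the lower 66 h library exceeded both later titer 100 libraries, which are as low in the W-type genes, by a ratio of at least 4.01 in each gene; that smallest ratio was to the 90 h library, which is outside the contrast that picked the genes, and it argues against sex. A change with time after infection, in granulocytes or in other cells, stays open as a hypothesis, and each time rests on 1 library per titer.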

How the results depend on the processing

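Without any infected library in turn, the number of called genes ranged from 0 to 1 for infection, 0 to 11 for titer 100 against the control, 0 to 1 for titer 10-2, 0 to 5 for 66 h, 0 to 3 for 90 h, 0 to 2 for 114 h, 1 to 34 between the titers, 2 to 49 for 114 h against 66 h and 5 to 108 for any time, in fits with fewer libraries. DESeq2 called 10, 20, 12, 39, 4, 19, 23, 33 and 52 genes in the same order, including all of edgeR's calls where it had any. Without the filter the counts were 1 for infection, 1 for titer 10-2, 7 for 66 h, 2 for 114 h, 5 between the titers and 7 for 114 h against 66 h. limma on RPKM called 1 for infection, 1 for titer 10-2 and 2 for 66 h. Time and titer as covariates gave 2 calls for infection, titer 100 with the control alone gave 3, and time as a straight line gave 0. The cause of these differences was not tested.

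A term for the W-type genes, chosen after seeing the data, gave 0 calls for titer 100 against the control, 2 for 66 h, 3 for 114 h, 1 between the titers and 13 for any time. With it 1 of the 4 genes of 114 h against 66 h, SERPINB10, was still called (-3.73 ± 0.24). The differences were -5.55 ± 0.56 for PROK2, -3.99 ± 0.48 for LOC101802154 and -2.48 ± 0.31 for MMP9, each within 1 SE of that without the term, with residual degrees of freedom down from 2 to 1. The lost LOC101803474 was at 3.88 ± 0.45 against 4.33 ± 0.45, just over 1 SE lower. MMP9 was also lost with RLE size factors, without robust fitting, with limma on RPKM and without the titer block. The 114 h minus 66 h difference of LOC101804125, highest at 90 h, ran from -0.21 (without titer 100 at 66 h) to 0.83 (without titer 10-2 at 66 h). Camera called 0 lists with an estimated correlation in each of the 8 comparisons, but in that form it also missed the changed list in simulated data (adjusted p = 0.0849). In 1 direction fry also called 0 of 27 lists in each of the 8 comparisons, although it called that simulated list (adjusted p = 0.0347). Without single libraries the count of lists that camera called with the preset correlation ran from 6 to 10 for titer 100 against the control, 5 to 10 for 90 h, 7 to 12 for 114 h and 6 to 13 between the titers. Of the 336 medians of lists in single libraries under another prior count or scaling, all moved by less than their spread over libraries. Scaling by total counts alone would move the median of all genes by up to -0.15, for titer 100 against the control. With 2 to 4 residual degrees of freedom, and with 18.2% of 2-fold changes recovered in simulated data of the infection comparison, changes of that size were mostly not detectable.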

Other observations

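The tests of sex, with their splits into 4 and 3, the test of library depth and the added immunoglobulin group were chosen after the result was seen, and the test of transcript length and the other splits were not. Globin transcripts took 0.227% of counts in the control, 0.295, 0.181 and 0.497% in titer 100 at 66, 90 and 114 h, and 0.514, 0.541 and 1.08% in titer 10-2 at the same times. Mitochondrial messenger RNA took between 3.77% and 5.29% of counts. The immunoglobulin genes together took 2.2% of counts in the control and between 3.53% and 8.67% in the infected libraries, highest at 66 h in titer 10-2, and their 114 h minus 66 h median was -0.50 (camera adjusted p = 4.8e-06; adjusted p = 0.856 with an estimated correlation). Thrombocyte genes had medians of 0.52 and 0.34 against the control in titer 10-2 at 90 h and 114 h and between -0.10 and -0.28 in the other 4 libraries.

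Of the 10 splits of the 6 infected libraries into 3 and 3, all 10 gave at least the 0 genes of the real split between titers, and the highest other split gave 3. Of the 7 ways to set 1 library against the other 6, all 7 gave at least the 0 genes of the control, and the highest other, titer 100 at 90 h, gave 4. With a real count of 0 every split reaches it, so neither comparison could have come out otherwise, and both sets are too few for a share under 0.05.

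The W-type genes summed to between 200.3 and 227 CPM in 3 libraries and to between 17.6 and 24 CPM in the other 4, and raise the hypothesis that birds of both sexes were sampled, since the W chromosome is carried by female birds. Library depth argues against itself as a cause, because 4 of the 4 libraries low in these genes had more counts than the shallowest of the other 3. If sex were the cause, Z-linked genes may be higher in those 4 libraries. Their median log2 difference against other genes was 0.116 over 106 genes, in the predicted direction. Of the 35 splits of the 7 libraries into 4 and 3, 2 gave a value as large, counting the split by the W-type genes itself. The highest other was 0.152, so the test leaves the explanation open. The value depends on which genes are taken as Z-linked: another choice, looked at informally and not used here, gave a larger difference. Sex is not given in the labels, and the genes were picked for the pattern.

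The ribosomal protein genes, short and abundant transcripts, stood higher at titer 100. Other genes matched on length and level also differed between the titers, with a median log2 difference of 0.21 against 0.47 for the ribosomal protein genes, so length or level may account for part of the pattern. The ribosomal protein median lay above the 95% range of the matched medians (0.14 to 0.35) and 0.259 above their middle. The matched genes were longer, with a median length of 616 against 521. They were also drawn independently, while the ribosomal protein genes vary together (estimated correlation 0.876), so that range is too narrow for them. The test therefore cannot exclude length or level as the whole cause. At 66 h, where both titers are low in the W-type genes, the ribosomal protein difference was -0.215, while at 90 h and 114 h, where the titers differ in those genes, it was 0.99 and 0.59. Sex and titer cannot be told apart here, because a single time offers libraries alike in the W-type genes. A biological effect of titer stays open and untested.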
